A study of Mus musculus with 12 samples.

How the data were processed

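RNA of 12 whole placentas was sequenced as paired-end libraries made with a directional kit, per the labels' protocols, which name poly(A) RNA as the molecule. Values were deposited by the authors as TPM in one table with 1 column per library. TPM scales reads by gene length and by the library total, and each of the 12 columns sums to 1e+06. DRAGEN and the genome build GRCm39 are named in the submitters' processing notes. The version, annotation, trimming and any filter are not given in the sources used here. The table pairs no identifiers with its gene symbols. It lists 0 mitochondrially encoded genes. Because TPM keeps no depth, no counting error can be given, and low genes may be less precise than their SD shows.

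Libraries were grouped by genotype and fetal sex from their titles, with 3 libraries in each of 4 groups. The library names carry 3 numbers in WT (40, 50 and 42) and 4 in KO (27, 28, 35 and 26). These may mark litters, which the labels do not say. Placentas with the same number might share a dam, and p-values over 12 libraries would then be too small. No 2 libraries held identical values.

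The limma and list tests, gene lists, alternatives and named-gene rule were set before the data were examined. The exact permutation tests and the count at an unadjusted p around Fndc5 were not part of that design. That design provided for counts or for a normalized unit, and the TPM branch was used. Values were transformed as log2(TPM + 1), so that a log2 change understates the change of low genes. Genes with a mean of at least 1 TPM were kept, 12371 of 24972. Limma 3.58.1 in R 4.3.3 fitted 1 mean per genotype-by-sex group to all 12 libraries, with an intensity trend in the prior variance. Contrasts gave KO against WT over both sexes and within each sex, their difference, and male against female. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The median half-width of the 95% interval of a log2 change was 0.36 over both sexes and 0.51 within a sex.

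Of 44 lists fixed for cell types and pathways, 42 had at least 3 tested members. The mitochondrially encoded and the T and B lymphocyte lists had too few. Of the 848 listed symbols 830 were found. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 42 lists. Single values and list scores were tested with two-sided exact permutation tests over 6 against 6 libraries, within sex, and over means per library-name number. Named genes were Fndc5, the 5 smallest p of a contrast where fewer than 3 genes passed, the 5 smallest p for sex apart from sex-linked lists, and up to 4 members of a described list with the smallest p. Gcgr, Cxcl2, C1qa, C1qb, C1qc, Ide, Entpd4 and genes named by range were named because they passed over a list alone or after their values were seen. Neighbours of Fndc5 came from a RefSeq table of GRCm38, another build than that of the values, and 99.9% of tested genes had a position in it. No coordinates are given for that reason.

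The test was tried on simulated data, in which 50 of 12371 genes were changed at each of 4 sizes for KO against WT over both sexes. It recovered 74% at a log2 change of 1, 88% at 1.5 and 98% at 2 and at 3, with 7 false calls (3.76%). A simulated shift of the endothelium list was found and 0 other lists were called. The noise was drawn for each gene independently, while the lists called in the real data had estimated correlations above the preset one. The simulation therefore does not show how often camera calls lists falsely in these data. The recovery likewise holds for data with this many changed genes.

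Alternatives were a pseudocount of 0.1, no filter, haemoglobin genes left out, each library left out, the fetus number as a block, the library-name number as a random or fixed block or averaged, genotype without sex, fits within a sex, and other windows. For the lists, the pseudocount of 0.1 and leaving out haemoglobin genes were added only after the data were seen. Also added then were a filter at 10 TPM, median-ratio scaling, sample weights, leaving out both libraries numbered 50, and a term for or a restriction by non-polyadenylated RNA. The last used the summed TPM of 129 genes with such biotypes, which was between 115 and 198 in KO female 3 and the 3 KO males and between 22.1 and 50.0 in the other 8 libraries. The size factors, tests and surrogate variable laid down for counts were not run on these TPM values, and surrogate variables on log values were not tried. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.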

Results

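Messenger RNA of whole mouse placentas was profiled at gestational day 17.5, late in mouse pregnancy. The 12 libraries came from 6 wild-type (WT) and 6 Fndc5 knockout (KO) placentas, with 3 female and 3 male fetuses of each genotype. Fndc5 codes for a membrane protein from which the secreted peptide irisin is released. The values are TPM, read numbers scaled by gene length and library total, which keep no read depth, so the depth of each library is unknown. Each library had between 17185 and 17927 genes above 0 TPM. Of the 24972 genes in the table, 12371 had a mean of at least 1 TPM and were tested. Haemoglobin genes took between 3.72% (KO female 3) and 35.2% (KO female 2) of TPM per library.

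The targeted gene was examined first. Fndc5 was at 30.1 ± 18.8 TPM in WT (SD, n = 6) and at 14.3 ± 2.92 TPM in KO (SD, n = 6), so that the KO mean was 47.4% of the WT mean. The WT females were at 24.7, 67.7 and 21.5 TPM and the WT males at 17.0, 20.8 and 29.1 TPM. The KO females were at 14.1, 15.1 and 18.6 TPM and the KO males at 11.0, 11.1 and 15.7 TPM. All 6 KO libraries lay below the WT mean, although the ranges of the genotypes overlapped. A two-sided exact permutation test of log2(TPM + 1) over the 6 WT and 6 KO libraries gave p = 0.0043. Permuting genotype within sex gave p = 0.005 in an exact test, the smallest p that this test can give. Across all genes the change did not pass (log2 change -0.89, SE 0.25, limma adjusted p = 0.70). WT female 2 had the highest level, and without it the KO mean was 63.1% of the WT mean. The values cover the whole gene, so which part of it is still transcribed in the KO could not be read from them. KO female 2 carries WT in its library name and KO in its title and column name. The labels state that the WT in its library name is an error. Its Fndc5 level of 15.1 TPM lay within the range of the other KO libraries.

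**Figure D1:**
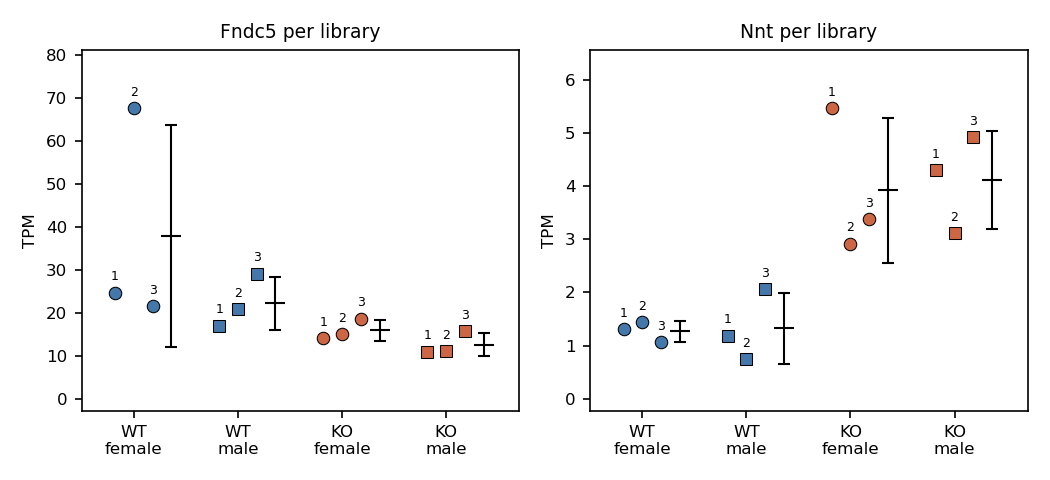
Level in TPM of Fndc5 (left) and Nnt (right) in each library by genotype (blue WT, orange KO) and fetal sex, with circles for females, squares for males and the fetus number above each point, and bars beside each group for the mean with its SD (n = 3). For Nnt all 6 KO libraries lie above all 6 WT libraries, while for Fndc5 the genotypes overlap and WT female 2 stands at 67.7 TPM.

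The design asks which genes are altered by loss of Fndc5. Over both sexes 1 gene passed the threshold, and 2 passed without WT female 3 or KO male 1. The histone H4 gene Hist1h4m was at 8.85 ± 2.38 TPM in WT (SD, n = 6) and at 0.732 ± 0.858 TPM in KO (SD, n = 6; 0.475 TPM without KO female 2). Its log2 change was -2.62 (SE 0.27, limma adjusted p = 0.0035), and all 6 KO libraries lay below all 6 WT libraries. Hist1h4n, a second histone H4 gene, did not pass (log2 change 2.55, SE 0.45, limma adjusted p = 0.34). Hist1h4n was listed at 0 in 5 WT libraries and at 8.50 TPM in WT female 3. It was at 5.46, 6.59 and 8.79 TPM in the KO females and at 6.33, 7.63 and 11.4 TPM in the KO males. The summed TPM of both genes was 10.3 ± 3.46 in WT and 8.43 ± 2.21 in KO (SD, n = 6 each), a difference within the spread of the libraries. Histone H4 genes code for the same protein and are closely alike in sequence, so the values of each single copy are uncertain.

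**Figure D2:**
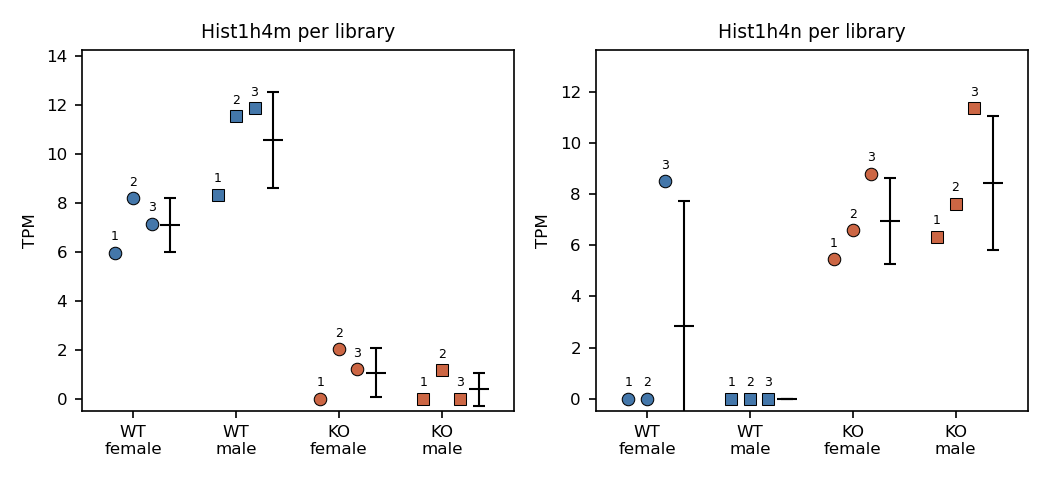
Level in TPM of Hist1h4m (left) and Hist1h4n (right) in each library by genotype (blue WT, orange KO) and fetal sex, with circles for females, squares for males and the fetus number above each point, and bars beside each group for the mean with its SD (n = 3), where the Hist1h4n bar of the WT females runs below the axis. Hist1h4m is lower in all KO libraries than in all WT libraries, and Hist1h4n is listed at 0 in the WT libraries other than WT female 3.

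The other genes with the smallest p in this comparison did not pass the threshold. Nnt, which codes for the mitochondrial nicotinamide nucleotide transhydrogenase, was at 1.30 ± 0.439 TPM in WT and 4.02 ± 1.04 TPM in KO (SD, n = 6 each; log2 change 1.12, SE 0.18, limma adjusted p = 0.19). Slc14a1, a urea transporter, was at 1.37 ± 0.909 TPM in WT and 4.74 ± 1.01 TPM in KO (SD, n = 6 each; limma adjusted p = 0.34). Bhmt2, a methyltransferase that makes methionine, was at 0.362 ± 0.259 TPM in WT and 1.65 ± 0.541 TPM in KO (SD, n = 6 each; limma adjusted p = 0.34). For Nnt, Slc14a1 and Bhmt2 all KO libraries lay above all WT libraries. Such a complete separation occurred in 27 genes, 0.218% of those tested, and chance gives 0.216%. At an unadjusted p under 0.05 there were 531 genes, where 618.55 would be expected by chance. Hist1h4m no longer passed with a pseudocount of 0.1 (adjusted p = 0.23), with no low-value filter (adjusted p = 0.062), with a term for libraries high in non-polyadenylated RNA (log2 change -2.85, SE 0.49 in place of 0.27, adjusted p = 0.48) or on the means per library-name number (adjusted p = 0.19). Over all alternatives that tested it, its log2 change lay between -4.48 and -2.40 and its adjusted p between 0.00068 and 0.48.

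The 44 gene lists fixed beforehand described placental cell types and pathways, and 42 had enough tested members. The competitive test camera with its preset correlation called 14 lists, 7 higher and 7 lower in KO, and 24 without WT female 2. With the correlation estimated from the data camera called 0 lists, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.47. No list passed the directional fry test (1 at an unadjusted p under 0.05, smallest adjusted p = 0.72). The preset correlation was 0.01, while the estimated correlations of the 14 called lists lay between 0.10 (angiogenic factors) and 0.89 (yolk sac endoderm).

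Genes of the yolk sac visceral endoderm, the absorptive epithelium of the yolk sac, stood out among the lists that were higher in KO. All 16 tested members had a log2 change above 0, with a median of 2.20, and 0 passed over all genes. Adjusted over the list alone 13 passed, among them the fibrinogen chains Fgg, Fgb and Fga and the serine protease inhibitor Spink1. Fgg was at 11.7 ± 16.4 TPM in WT and 49.4 ± 39.5 TPM in KO (SD, n = 6 each), and Spink1 was at 24.2 ± 28.5 TPM in WT and 95.1 ± 82.3 TPM in KO (SD, n = 6 each). Without WT male 3 the WT means were 5.40 TPM for Fgg and 13.7 TPM for Spink1. KO female 1 and KO male 1, whose library names share the number 27, had the highest Fgg levels at 112 and 85.5 TPM. In the other KO libraries Fgg lay between 16.6 and 28.7 TPM, below WT male 3 at 43.4 TPM. The list score, the mean log2(TPM + 1) of the members, was 3.91 ± 1.60 in WT and 5.82 ± 1.05 in KO (SD, n = 6 each). An exact permutation of genotype within sex gave p = 0.03 for this score, and p = 0.61 after adjustment over the 42 lists. An exact permutation of the means per library-name number gave p = 0.029 before adjustment, the smallest p that this test can give. With an estimated correlation the list had an adjusted p = 0.47. The highest scores were those of KO female 1 (7.54) and KO male 1 (6.72). The other KO libraries lay between 5.02 and 5.31, below WT male 3 at 6.18. The lowest score was that of WT male 2 at 1.63. Without that library the list median was 1.34 over both sexes, and in males it was 0.021 in place of 1.54, with the call lost (adjusted p = 0.84). Without KO male 1 the male call was also lost (median 1.03, adjusted p = 0.45), and without WT male 3 the male median was 2.56. Within the 5 female libraries low in non-polyadenylated RNA the score difference was 2.81 (SE 0.99), beside 2.47 (SE 0.84) in all 6 females.

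Both syncytiotrophoblast lists were called lower in KO by camera with the preset correlation, and neither with an estimated one. This fused cell layer of the labyrinth carries exchange between mother and fetus. In layer II all 10 members had a log2 change below 0 (median -0.66), and 5 passed adjusted over the list alone, with 0 over all genes. They were Synb, the fusion protein of this layer, Gcm1, the transcription factor that starts its formation, the lactate transporter Slc16a3, the homeobox factor Dlx3 and the glucagon receptor Gcgr. Synb was at 68.8 ± 84.0 TPM in WT and 5.31 ± 6.24 TPM in KO (SD, n = 6 each; log2 change -3.10, SE 0.70, limma adjusted p = 0.63). Its WT mean was 39.6 TPM without WT female 2, and its KO mean 3.42 TPM without KO female 3. In layer I 6 of 7 members were below 0 (median -0.42), and the sulphate transporter Slc13a4 and the transferrin receptor Tfrc passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.47 for layer II and 0.53 for layer I. An exact permutation within sex of the list scores gave an adjusted p = 0.61 for each, and an exact permutation of the means per library-name number gave p = 0.14 for each before adjustment. The layer II score was 4.37 ± 0.775 in WT and 3.40 ± 0.548 in KO (SD, n = 6 each), and WT female 2 and WT female 3 had the highest scores at 5.49 and 5.06. Without WT female 2 the score difference went from -0.96 (SE 0.37) to -0.77 (SE 0.36). Within the 5 female libraries low in non-polyadenylated RNA it was -1.76 (SE 0.65). WT female 2 also had the lowest spongiotrophoblast score of the WT libraries, 8.71 with the others between 10.4 and 11.0.

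The interferon response and inflammatory cytokine lists were called lower in KO by camera with the preset correlation, and neither with an estimated one. Of 26 interferon response genes 25 had a log2 change below 0 (median -0.50), and of 18 inflammatory genes 17 had (median -0.46). None passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.63 for each list. The median of the interferon list was -0.24 without WT female 2 and -0.19 without WT male 2, and that of the inflammatory list was -0.14 without WT male 2, where it was no longer called (adjusted p = 0.12). The interferon score was 5.59 in WT male 2 and 5.08 in WT female 2, whose library names share the number 50, and between 3.49 and 4.20 in the other libraries. Without those libraries the KO minus WT difference went from -0.48 (SE 0.35) to 0.03 (SE 0.11), and that of the inflammatory score from -0.60 (SE 0.46) to -0.01 (SE 0.11). In the inflammatory list Cxcl2 was at 141 TPM in WT male 2, between 0.189 and 5.58 TPM in the other WT libraries and between 0.0597 and 0.400 TPM in the KO libraries. The neutrophil and granulocyte score was also highest in WT male 2 (5.28) and WT female 2 (4.33), and lay between 2.74 and 3.55 in the other libraries.

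**Figure D3:**
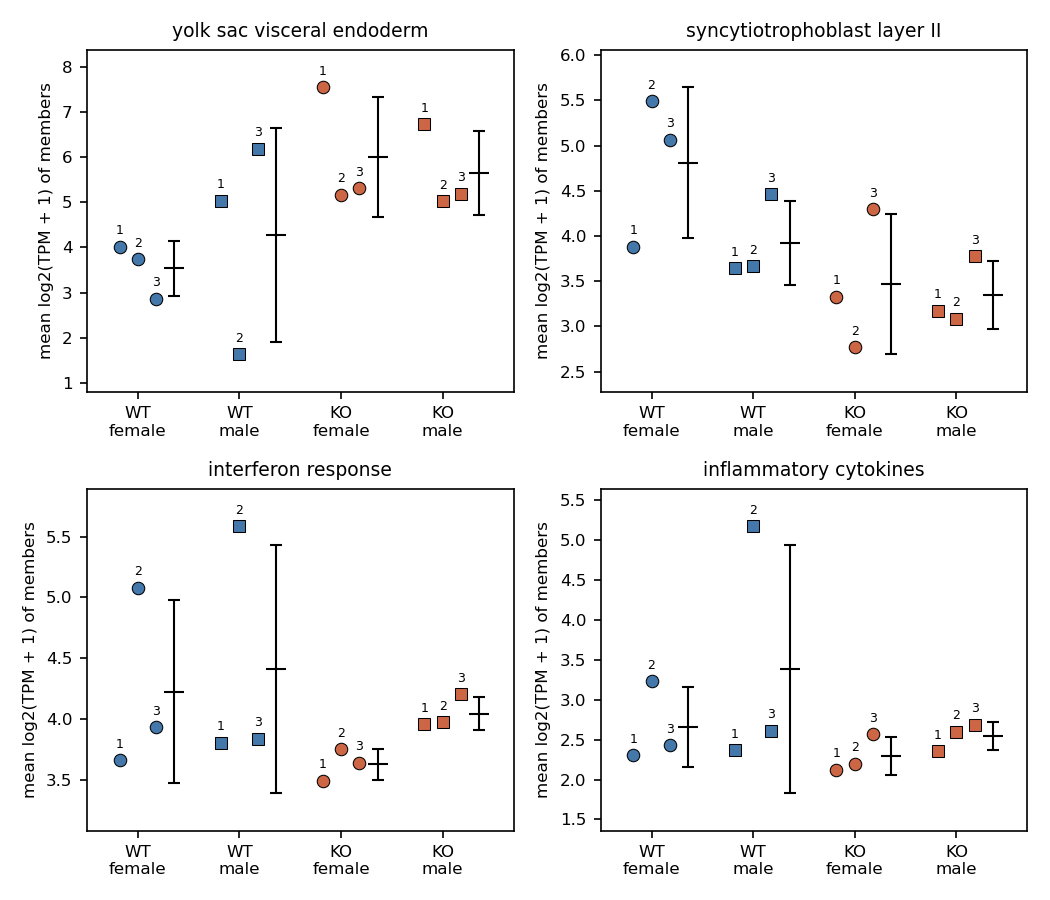
Score of 4 gene lists, the mean log2(TPM + 1) of the members, in each library by genotype (blue WT, orange KO) and fetal sex, on axes that do not start at 0, with circles for females, squares for males and the fetus number above each point, and bars beside each group for the mean with its SD (n = 3). WT male 2 has the lowest yolk sac score at 1.63, and WT male 2 and WT female 2 have the highest interferon scores at 5.59 and 5.08.

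Camera also called 9 other lists. Amino acid transport (median log2 change -0.42), endothelium (-0.24) and angiogenic factors (-0.18) were lower in KO. Slc7a5, a transporter of large neutral amino acids, was at 91.4 ± 70.0 TPM in WT and 38.1 ± 30.4 TPM in KO (SD, n = 6 each). The vascular endothelial growth factor receptor Kdr was at 18.9 ± 4.05 TPM in WT and 12.0 ± 2.25 TPM in KO (SD, n = 6 each), below all WT libraries in all 6 KO libraries, and passed adjusted over the list alone. Smooth muscle and myometrium (median 0.79), pericyte and stroma (0.33), cholesterol synthesis (0.21), cell cycle (0.20), oxidative phosphorylation (0.12) and ribosomal protein genes (0.11) were higher in KO. With an estimated correlation their adjusted p was 0.63 for amino acid transport, endothelium, cholesterol synthesis, cell cycle, smooth muscle and stroma, 0.47 for angiogenic factors and 0.85 for oxidative phosphorylation and ribosomal genes. A term for libraries high in non-polyadenylated RNA turned the camera direction of the endothelium, angiogenic and ribosomal lists. The medians of endothelium (-0.082) and angiogenic factors (-0.15) stayed negative, and the ribosomal median was -0.22. That term is estimated from KO female 3 against KO female 1 and KO female 2 alone. Without WT female 2 the endothelium median was -0.13, and the smooth muscle median was 0.45 without WT male 2 and 0.51 without KO male 3. Camera no longer called the stroma list without WT female 2, WT male 3, KO female 1, KO female 2, KO male 2 or KO male 3 (medians between 0.17 and 0.29). It no longer called oxidative phosphorylation without WT female 1, WT female 3, WT male 1 or KO male 3 (0.0067 to 0.088), ribosomal proteins without WT female 1, WT male 1, WT male 3, KO female 3 or KO male 3 (0.016 to 0.14), or cholesterol synthesis without WT female 2 (0.18). Without WT female 2 the medians were 0.22 for oxidative phosphorylation and 0.23 for ribosomal proteins, and the ribosomal median was 0.17 without KO female 2 and 0.18 without KO male 1. Oxidative phosphorylation had a median of 0.077 without KO female 3, and stroma one of 0.20 without WT male 2. The cholesterol median was 0.14 without WT male 2. The thermogenic and PGC-1alpha list was not called (median 0.14, adjusted p = 0.098), nor was the list of Fndc relatives and irisin receptor integrins (median -0.07, adjusted p = 0.19).

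A knockout line can carry DNA of another strain beside the targeted gene. Of 237 tested genes within 10 Mb of Fndc5, 0 passed the limma threshold, and 10 had an unadjusted p under 0.05 (4.22%, against 4.28% outside). A two-sided Fisher's exact test of the latter shares gave p = 1. Among those 10 genes were the complement genes C1qa, C1qb and C1qc (limma unadjusted p between 0.020 and 0.024). The test counts them as separate genes. In the list of genes known to differ in copy number or by deletion between mouse strains, fry found change in either direction over both sexes (adjusted p = 0.00073), and did not within females (adjusted p = 0.071) or males (adjusted p = 0.90). Adjusted over the list alone Nnt, Ide and Entpd4 passed. Ide, the insulin-degrading enzyme, was at 12.5 ± 3.11 TPM in WT and 20.8 ± 9.28 TPM in KO, and Entpd4, a Golgi nucleotidase, was at 3.01 ± 1.73 TPM in WT and 1.49 ± 1.71 TPM in KO (SD, n = 6 each; KO mean 0.995 TPM without KO male 1).

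The titles allow the comparison within each fetal sex. In females limma called 0 genes, with 419 at an unadjusted p under 0.05 and a smallest adjusted p of 0.70. Without WT female 1 it called 3 genes and without WT female 3 it called 1. The smallest p belonged to Hist1h4m, Ggta1, Dmkn, Htra1 and Klk6. Dmkn, a secreted epidermal protein, was at 364 ± 158 TPM in WT females and 108 ± 30.1 TPM in KO females (SD, n = 3 each), and the serine protease Htra1 was at 171 ± 66.9 and 45.7 ± 24.9 TPM (SD, n = 3 each). Only 2 KO and 3 WT female libraries were low in non-polyadenylated RNA, and a fit on the low libraries called 1 gene. In males limma called Hist1h4m alone (log2 change -3.15, adjusted p = 0.022), with 218 genes at an unadjusted p under 0.05. It called 0 genes in males when WT female 1, any WT male or KO male 3 was left out, and 2 without WT female 3 or KO female 3. Without KO male 1 it called 1 gene, higher in KO, and not Hist1h4m (adjusted p = 0.093). The next genes were Hist1h4n, Akr1b3, Nnt and Krt23, none past the threshold. Akr1b3, the aldose reductase, was at 2.46 ± 0.552 TPM in WT males and 9.96 ± 4.47 TPM in KO males (SD, n = 3 each). All 3 KO males were high in non-polyadenylated RNA and no WT male was, so genotype and that difference could not be told apart in males. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1.

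Camera called 13 lists in females and 21 in males, and 0 in either sex with an estimated correlation (smallest adjusted p = 0.38 and 0.57), where 3 lists in females and 1 in males had an unadjusted p under 0.05. In females yolk sac endoderm was higher in KO (median log2 change 2.59, adjusted p = 0.38 with an estimated correlation) and syncytiotrophoblast layer II lower (-1.17, adjusted p = 0.38 with an estimated correlation; median -0.71 without WT female 2). In males smooth muscle was higher (median 1.31) and so were macrophage genes (0.42), both with an adjusted p = 0.57 with an estimated correlation. The smooth muscle median in males was 0.64 without WT male 2, 0.67 without KO male 3, 2.0 without WT male 3 and 2.02 without KO male 1. That of macrophage genes was 0.16 without KO male 3, 0.66 without WT male 2 and 0.66 without KO male 1, and without WT male 3 the list was no longer called (median 0.32, adjusted p = 0.39). The complement genes C1qa, C1qb and C1qc passed adjusted over the macrophage list alone in males. All of them also lie within 10 Mb of Fndc5 in GRCm38. Whether their change came with macrophages or with DNA beside the targeted gene was not tested.

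The sex difference of the knockout effect was tested as an interaction. Limma called 0 genes, with 77 at an unadjusted p under 0.05 and a smallest adjusted p of 0.78, and it called 1 gene without KO male 1. The smallest p belonged to Akr1b3, Gm5643, Dmkn, Cldn10 and Ntn4. The log2 change of Akr1b3 was higher by 2.74 (SE 0.47) in males. Its direction differed between the sexes, as it was lower in KO females (2.53 ± 1.31 TPM) than in WT females (6.67 ± 2.17 TPM; SD, n = 3 each). Camera called 16 lists and 0 with an estimated correlation (smallest adjusted p = 0.54, 1 list at an unadjusted p under 0.05). Without WT female 2 or WT male 2 it called 10 lists. Median-ratio scaling moved the median of all genes in this contrast from 0.14 to -0.03 and the number of called lists to 9.

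Male and female placentas differed in sex-linked genes. Limma called 7 genes, 6 higher and 1 lower in males, and 13 without KO male 1. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were higher in males (log2 changes between 1.80 and 4.08), and Xist, the RNA that silences an X chromosome, was lower (log2 change -2.26, limma adjusted p = 0.044). The call of Xist ended in 16 of 22 alternatives (limma adjusted p up to 0.34), among them leaving out any 1 library other than KO female 2. Its log2 change lay between -2.53 and -1.97 when single libraries were left out, and at -2.26 with the replicate block (limma adjusted p = 0.077). Ddx3y lay between 9.84 and 19.4 TPM in males and between 0 and 0.0852 TPM in females. The sex labels and these genes went together in all 12 libraries. The other calls were the histone gene Hist1h2br (log2 change 1.43, limma adjusted p = 0.0027) and the small nucleolar RNA host gene Snhg15 (log2 change 1.11, limma adjusted p = 0.0045). With a term for non-polyadenylated RNA neither passed, as the SE grew while the log2 change stayed about as large. Hist1h2br then had a log2 change of 1.43 (SE 0.21 in place of 0.17, limma adjusted p = 0.063) and Snhg15 one of 1.11 (SE 0.17 in place of 0.14, limma adjusted p = 0.068). Snhg15 also missed the threshold with the library-name number as a fixed block (log2 change 1.05, SE 0.16, limma adjusted p = 0.13). Snhg15 was at 1.64 ± 0.280 TPM in females and 4.76 ± 0.990 TPM in males (SD, n = 6 each). Mal, Gng10 and Upk3bl followed without passing.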

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

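The tests of the yolk sac pattern on WT male 2, batch and genotype, those of the interferon pattern on the libraries numbered 50 and genotype, and those of the Nnt pattern on strain, batch and genotype were set against these patterns after the results were seen, while camera with either correlation and limma had been laid down before. Outliers were sought by Dixon's criterion in 98 sets of 6 libraries, of which chance flags about 1 in 20, and 6 were found. In WT female 2 the spongiotrophoblast score was 8.71, with the other WT libraries between 10.4 and 11.0. Its score of pregnancy-specific glycoprotein and Ceacam genes was 7.90, with the others between 10.1 and 10.6, and its maternal decidua score was 3.98, with the others between 4.82 and 5.22. Its Fndc5 level was 67.7 TPM, with the others between 17.0 and 29.1 TPM. In WT male 2 the inflammatory score was 5.17, with the others between 2.31 and 3.23. In WT female 3 Hist1h4n was at 3.25 on the log2(TPM + 1) scale and listed at 0 in the other WT libraries.

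For 16 lists the knockout effect differed between the sexes by camera with the preset correlation, and for 0 with an estimated correlation (smallest adjusted p = 0.54). The median difference, males minus females, was -0.82 for pregnancy-specific glycoprotein and Ceacam genes, -0.69 for spongiotrophoblast, -1.11 for yolk sac endoderm, -0.28 for inflammatory cytokines, -0.11 for the prolactin family, -0.12 for the unfolded protein response, -0.51 for uterine natural killer cells, -0.28 for parietal giant cells, -0.14 for cathepsins and serpins and -0.21 for neutrophils. It was 0.31 for oxidative phosphorylation, 0.33 for ribosomal proteins, 0.70 for macrophages, 0.85 for syncytiotrophoblast layer II, 0.34 for endothelium and 1.04 for smooth muscle. Leaving out single libraries ended or moved most of these calls. Yolk sac endoderm alone kept its call and direction in all 12 such fits, with medians of -2.54 without WT male 2, -0.34 without KO female 1 and -0.28 without WT male 3. Without WT female 2 camera called 10 lists, and the calls ended for pregnancy-specific glycoprotein and Ceacam genes (0.015), spongiotrophoblast (0.034), parietal giant cells (-0.094), cathepsins and serpins (-0.081), the unfolded protein response (0.056), the prolactin family (0.049), oxidative phosphorylation (0.093), ribosomal proteins (0.11), layer II (0.35), endothelium (0.049) and smooth muscle (0.88). Without WT male 2 it called 10, and the calls ended for parietal giant cells (-0.19), the prolactin family (-0.0090), cathepsins and serpins (-0.16), natural killer cells (0.21), neutrophils (0.80), layer II (0.78), endothelium (0.30) and smooth muscle (0.31), while inflammatory cytokines were called in the other direction (0.52). Leaving out WT female 1 ended the calls of endothelium (0.41), macrophages (0.67), neutrophils (0.19) and smooth muscle (0.95), and KO female 3 those of cathepsins and serpins (0.060), endothelium (0.26), macrophages (0.67) and smooth muscle (0.79). Leaving out KO male 1 ended those of layer II (0.87), cathepsins and serpins (-0.037) and endothelium (0.32), and KO male 3 those of parietal giant cells (-0.12), neutrophils (-0.26) and smooth muscle (0.32). Layer II was also lost without WT female 3 (0.85) or KO female 2 (0.53), neutrophils without WT female 3 (0.034), KO female 1 (-0.12) or KO female 2 (-0.19), and endothelium without WT male 1 (0.20). Ribosomal proteins were lost without WT male 1 (0.16) or WT male 3 (0.35), macrophages without WT male 3 (0.52) and smooth muscle without KO male 2 (0.79). Medians that moved by over 1.5 times with the call kept ran from -1.32 (WT female 3 left out) to -0.54 (KO female 3) for pregnancy-specific glycoprotein and Ceacam genes, -1.15 (WT female 3) to -0.45 (KO female 3) for spongiotrophoblast, -0.67 (WT male 1) to -0.13 (KO male 1) for inflammatory cytokines, -0.40 (WT female 3) to -0.0058 (KO female 3) for the prolactin family and -0.26 (WT female 3) to 0.075 (KO female 3) for the unfolded protein response. They ran from -1.29 (WT male 3) to 0.32 (WT female 1) for natural killer cells, -0.18 (KO male 1) to 0.0049 (KO female 3) for parietal giant cells, -0.37 (WT female 3) to -0.056 (WT female 1) for cathepsins and serpins, -0.52 (WT male 1) to -0.48 (WT female 2) for neutrophils, 0.18 (KO male 3) to 0.52 (WT female 1) for oxidative phosphorylation and 0.18 (KO female 2) to 0.50 (WT female 1) for ribosomal proteins. The macrophage median was 0.29 without KO male 3, that of layer II 1.28 without WT female 1, that of endothelium 0.51 without WT male 3, and that of smooth muscle 1.74 without WT male 3 and 1.77 without KO male 1. For natural killer cells, parietal giant cells and the unfolded protein response, camera still placed the list lower where the median lay above 0 with the call kept.

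Camera with the preset correlation called yolk sac endoderm genes higher in KO, and not with an estimated one (adjusted p = 0.47 with an estimated correlation). A second list of 20 endoderm genes, 17 of them tested, was written before its values were seen. Its score followed the first within groups with r = 0.97, consistent with a varying amount of yolk sac endoderm in the tissue pieces, and its own KO minus WT difference was 0.83 (SE 0.31), but the correlation does not test whether KO pieces held more. Without WT male 2 the difference was 1.39 (SE 0.70), which neither keeps nor removes the pattern, and within the low non-polyadenylated female libraries it was 2.81 with a 95% interval from -0.35 to 5.98. Loss of Fndc5 stays open, as an exact permutation of the means per library-name number gave p = 0.029, the smallest it can give, while that within sex gave 0.61 adjusted over the lists, and no such number occurs in both genotypes.

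Camera with the preset correlation called interferon response genes lower in KO, and not with an estimated one (adjusted p = 0.63 with an estimated correlation). The 2 WT libraries numbered 50 lay above the other 4 with an exact permutation p = 0.067, the smallest that 15 pairs can give, so this test could not have passed 0.05 and decides nothing. Without them the difference was 0.03 (SE 0.11), but they were noticed by this very score, so whether they are its source stays open. Loss of Fndc5 also stays open (adjusted permutation p = 0.75).

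Nnt was higher in all KO libraries. C57BL/6J mice carry a known deletion in Nnt, and another strain background of the KO animals stays open. Among the genes with the smallest p over both sexes, Hist1h4m, Nnt, Hist1h4n and Bhmt2 lie on chromosome 13 in GRCm38. Slc14a1 lies on chromosome 18, and Fndc5 on chromosome 4. Whether the genes on chromosome 13 lie in DNA of another strain was not tested. The other 10 genes of the strain list gave p = 0.035 for a difference in either direction by an exact permutation within sex, but Ide and Entpd4 had already been seen to pass over this list, and the 8 genes without them gave p = 0.17, so this test decides nothing. More endoderm tissue as the whole cause was argued against, since the Nnt difference was 0.81 (SE 0.14) with the yolk sac score as covariate and 1.12 (SE 0.17) without. Within the low female libraries the Nnt difference was 1.15 (95% interval 0.24 to 2.06). There KO female 1 and KO female 2 were at 5.46 and 2.91 TPM, and the WT females between 1.06 and 1.44 TPM. This argues against the batch as the whole cause in females. A part in females stays open, as the interval reaches down to 0.24, and in males batch and genotype cannot be told apart. Loss of Fndc5 also stays open (limma adjusted p = 0.19).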

How the results depend on the processing

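Filters at 10 TPM, median-ratio scaling, sample weights, the libraries numbered 50 and the settings on non-polyadenylated RNA were chosen after seeing the data. For the lists this also holds for the pseudocount of 0.1 and for leaving out haemoglobin genes. TPM keeps no depth, so what depth limits could not be tested, and the size factors, tests and surrogate variable laid down for counts were not run on TPM, nor was a surrogate variable on log values. Library totals alone and a mean of 1 CPM equal the main setting for TPM, and mitochondrial genes are not in the values. The cause was not tested for the changes below, unless stated. The log2 change of Fndc5 stayed negative throughout (-1.11 to -0.64, adjusted p between 0.0023 and 1) and passed only with sample weights (-0.65). Sample weights called 3148 genes over both sexes, 3595 in females, 1664 in males, 2495 for the interaction and 2935 for sex. Regroupings with sample weights were run for the first of these counts alone, and 25 of 100 splits gave at least as many. The 1 gene over both sexes became 0 with a pseudocount of 0.1, no filter, a filter at 10 TPM (which removes it), the batch term and the means per library-name number, and 2 without the libraries numbered 50. The 1 gene in males became 0 with the first 4 of these, without haemoglobin, with median-ratio scaling and without the libraries numbered 50, and 4 in the 6 male libraries alone. The 0 genes in females became 1 in the libraries low in non-polyadenylated RNA, and the 7 genes for sex became 0 at 10 TPM, which removes low sex-linked genes. Leaving out single libraries gave 1 to 2 genes over both sexes, 0 to 3 in females, 0 to 2 in males, 0 to 1 for the interaction and 6 to 13 for sex, with the highest counts without WT female 3 or KO male 1 (both sexes), WT female 1 (females), WT female 3 or KO female 3 (males) and KO male 1 (interaction and sex). It gave 11 to 24 lists over both sexes (24 without WT female 2) and 10 to 20 for the interaction (10 without WT female 2 or WT male 2). An estimated correlation gave 0 lists in each of the 4 contrasts, and the interaction had 9 lists with median-ratio scaling and 9 without the libraries numbered 50.

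The camera direction of some lists reversed; values are list medians. Without the libraries numbered 50 these were, in females, -0.26 (spongiotrophoblast), -0.12 (prolactin) and -0.41 (Psg and Ceacam), in males, 0.0064 (parietal giant cells), 0.069 (prolactin), 0.27 (natural killer), 0.26 (neutrophil), 0.021 (yolk sac), 0.20 (interferon) and 0.093 (inflammatory), and for the interaction, -0.0061 (spongiotrophoblast), 0.13 (parietal giant cells), 0.18 (prolactin), -0.029 (Psg and Ceacam), 0.046 (natural killer) and 0.11 (inflammatory). With the batch term they were, over both sexes, -0.082 (endothelium), -0.15 (angiogenic) and -0.22 (ribosomal), in males, 0.24 (endothelium), 0.54 (natural killer), -0.25 (neutrophil), 0.17 (angiogenic) and -0.44 (interferon), and for the interaction, 0.52 (natural killer), -0.13 (neutrophil) and -0.45 (yolk sac). That term also reversed Uqcrh (-0.065), Rpl26 (-0.59), Rps11 (-0.00082), Rps3 (-0.18) and Rps2 (-0.041). It is estimated from KO female 3 against KO female 1 and KO female 2 alone, also for the contrasts in males. Leaving out single libraries gave ranges, in females, of -0.26 to 0.85 (spongiotrophoblast), -0.12 to 0.25 (prolactin) and -0.41 to 0.90 (Psg and Ceacam), in males, of -0.21 to 0.012 (parietal giant cells), -0.20 to 0.069 (prolactin), -1.25 to 0.27 (natural killer), -0.82 to 0.26 (neutrophil), 0.021 to 2.56 (yolk sac), -0.62 to 0.20 (interferon), -0.92 to 0.093 (inflammatory) and 0.070 to 0.32 (cholesterol), and for the interaction, of -0.40 to 0.049 (prolactin), -0.52 to 0.80 (neutrophil), -0.67 to 0.52 (inflammatory) and 0.049 to 0.51 (endothelium). Reversals came from WT female 2 in females and mostly from WT male 2 in males. Of 1974 alternative values of named genes 1866 kept their direction and side of the threshold, 35 no longer passed, 68 newly passed and 5 reversed. Of 1216 values of called lists 964 kept both, 209 no longer passed and 43 reversed.

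The fetus numbers did not pair the libraries: same-numbered libraries of the other genotype correlated with a median r of 0.07, 5 of 12 pairs were over 0.1, and 6 of 12 libraries correlated best with their own number. Pairs sharing a library-name number had a median r of 0.28 (3 of 5 over 0.1), against -0.08 for pairs of one genotype with other numbers (3 of 13 over 0.1). With the replicate block limma called 1 gene over both sexes, 0 in females, 1 in males, 0 for the interaction and 6 for sex, and camera called 14, 11, 20 and 14 lists. Fndc5 stayed at -0.89 with an adjusted p of 0.42.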

Other observations

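The test of the female and male correlation and the sample-weight setting were chosen after the data were seen, while the regroupings of the counts, those with sample weights included, were laid down before their results. Some lists not yet described held single genes that passed adjusted over the list alone and not over all genes. Igfbp1, an insulin-like growth factor binding protein in the maternal decidua list, had a log2 change of 2.12 (SE 0.56) in KO. The score of that list differed by 0.04 (exact permutation within sex p = 0.83), so Igfbp1 does not show a change of decidua. Epcam, a surface protein of labyrinth progenitors, had a log2 change of 0.50 (SE 0.15), and Stbd1, a glycogen-binding protein, 0.68 (SE 0.19). In KO females Rrm1 and Rrm2, subunits of ribonucleotide reductase, had log2 changes of -0.81 and -1.11. The cell cycle list as a whole was called higher in KO females by camera with the preset correlation (median 0.16, adjusted p = 0.84 with an estimated correlation). That call ended without WT female 2 (median 0.23), WT female 3 (0.042), KO female 1 (0.17) or KO female 2 (0.15). These genes were chosen after their values were seen.

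The log2 changes of females and males correlated across genes with r = 0.51, although genes are not independent replicates, and 52.2% of the genes had the same sign in both sexes. Among 100 splits of genotype within sex, 1 gave as high a value, the real one, and the highest of the others was 0.508. The real value was thus the highest of the splits drawn, a share under 5%, by a narrow margin. Female and male libraries mostly share library-name numbers, which the splits do not keep together. Chance differences between numbers are therefore not excluded, and a source shared by libraries of one number stays open beside genotype.

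For KO against WT over both sexes, 6 of 100 splits gave as many genes as the real 1, with 1069 as the highest other, so chance could not be excluded. In females all 10 splits gave at least the real 0 (highest other 0) and in males 2 of 10 gave at least the real 1 (highest other 18), and 10 splits are too few for a share under 0.05. For the interaction all 100 splits gave at least 0 genes (highest other 805). For sex 2 of 100 splits gave at least 7 genes (highest other 499), a share under 5%. Most of these 7, the Y-linked genes and Xist, follow fetal sex by nature, so that share was largely fixed in advance. It does not test the calls of Hist1h2br and Snhg15. The splits with 1069, 805 and 499 genes call far more than the real ones and point to a structure of the libraries that follows neither genotype nor sex. Such splits were rare: 94, 96 and 97 of the 100 splits in these comparisons called 0 genes, the real interaction grouping included. In the split with 1069 genes the syncytiotrophoblast layer II score lay between 2.77 and 3.88 on the side of WT female 1. On the side of WT female 2 it lay between 3.64 and 5.49. This score was chosen after the split was seen, and what the structure is was not tested. In the splits with 1069, 805 and 499 genes WT female 1 and KO female 2 stood against WT female 2, WT female 3 and KO female 3. KO male 1 stood with WT female 1 in the splits with 1069 and 499 genes. In the interaction split with 805 genes, where males count with the opposite sign, KO male 1 counted with WT female 2.

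For the gene lists, 86 of 100 splits called at least the real 14 lists over both sexes (highest other 28), and 75 of 100 at least the real 16 of the interaction (highest other 28). Chance could not be excluded for either, and the median of the other splits was 18 lists. In females 10 of 10 splits gave at least 13 lists (highest other 25) and in males 3 of 10 at least 21 (highest other 25), too few for a share under 0.05. With sample weights 25 of 100 splits gave at least the real 3148 genes, with 7252 as the highest other, so that chance could not be excluded for that count. The weights ran from 0.123 for WT female 2 to 48.8 for KO female 1.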
